A study of Homo sapiens with 6 samples.

How the data were processed

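Gene expression was measured on 6 one-colour arrays hybridized with biotin-labelled cRNA from A549 cells, an established human lung adenocarcinoma cell line. Per the labels' protocols, total RNA was extracted with Trizol, and 100 ng of it was amplified and labelled. The design text of the series speaks of RNA sequencing, but the series is recorded as an array study and the table holds array values, so the data were treated as array data. Each of the 2 groups has 3 arrays. The titles name the groups (control and LINC00525) and number the replicates 1 to 3, and the treatment text describes a scrambled control. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

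The authors deposited log2 values for 49372 probe sets. RMA (background correction, quantile normalization across arrays and summarization of probes into probe sets) is the only step named in the submitters' processing notes. Its software, its version and the annotation used with it are not given in the sources used here. The deposited log2 values have 2 decimals. The array medians were 5.10 to 5.11, so the arrays had already been brought to a common distribution and were not normalized again. A log2 difference after RMA is relative to the typical gene of the array: quantile normalization removes any change shared by most genes, and summarization understates differences near background. No detection calls were used, because the table holds none. No scanner files were used here.

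Probe sets were named through the platform annotation supplied with the table. Of the 49372 probe sets, 44994 had exactly 1 gene symbol, 1832 had several and 2546, which include 79 control probe sets, had none listed. Symbols were updated by gene identifier, which was found in the GRCh38.p14 gene table for 44967 of the 44994. Only probe sets with 1 symbol entered the gene-level fit. For the 11735 genes with more than 1 probe set, the one with the highest mean over all 6 arrays stood for the gene, which gave 18132 genes. Some genes of the fixed lists had no probe set of their own and are not analysed here. No coordinates are given, because no genome build is named for the table.

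The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2-sided, all 6 arrays, no covariate). P-values were adjusted by Benjamini-Hochberg over the 18132 genes, with an adjusted p under 0.05 as the threshold. Errors of log2 fold changes are standard errors of this fit, and errors of group means are standard deviations over 3 arrays. For LINC00525 and CDKN1A an exact permutation test on the 6 values was added. With 3 arrays against 3 its smallest possible p is 0.1. Figures were drawn with matplotlib 3.10.9.

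The 33 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 33 lists, and again with an estimated correlation and with fry. Camera asks whether the genes of a list shifted, on balance, up or down relative to other genes. A list whose genes moved both ways can therefore go uncalled. Fry asks whether the genes of a list moved, on balance, one way. The rule names every measured gene of a list built around the subject of the study, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 genes with the lowest p in each list described. Symbols of uncharacterised loci (LOC, open reading frame and clone names) were skipped in ranking the 12 rises and 12 falls. Members of a list in which 5 or fewer genes rose, or 5 or fewer fell, were also named. Of these, KITLG, SPRED2, LMNB1, SLC6A6, SLC7A5, MYC, KDM5B, CBX7, PFKFB3, PGAM1, SMAD7, BIRC5, DSP, GRHL2 and KRT8 lie outside the rule and were chosen after their values were seen, as were IFNB1, IFNL1, IGFBP1 and UPP1.

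The pipeline was tested on simulated data with the control means and moderated spreads of these 18132 genes and 200 changed genes. It called 86.6% of the genes changed by 0.3 log2 units, 100% of those changed by 0.6 and 100% of those changed by 1. Of its 198 calls, 7 were false. The number of arrays limits the precision. Of 200 random lists of 30 genes drawn from simulated arrays with independent genes, 4% were called at an unadjusted p under 0.05.

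Arrays of 1 group correlated at 0.9983 to 0.9988, and arrays of different groups at 0.9960 to 0.9963. No pair of arrays had identical values at more than 4.81% of probe sets, so none was a copy of another. Same-numbered arrays of the 2 groups showed little sign of deviating together (correlations of deviations from the group means of 0.092, 0.058 and -0.010), so the numbers were not taken to pair the samples. Scores on the second principal component fell with the replicate number in both groups (3.86, -1.27 and -2.77 on control arrays, 8.82, -3.53 and -5.11 on knockdown arrays). A shared effect of the replicate number is therefore not excluded. No label gives a batch or date.

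The alternatives were 2 filters on mean signal (genes below the 25th percentile or below the median left out), 3 normalizations (quantile again, centring on the median, cyclic loess), the mean of a gene's probe sets or each probe set on its own in place of the brightest, eBayes with trend and robust settings, a linear model without moderation, array weights, the replicate number as a block, an adjusted p under 0.01 and leaving out each array. Scaling to the bacterial hybridization controls, scaling to the bacterial poly-A controls, and leaving out probe sets with the suffixes _s_at and _x_at were added after seeing the data.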

Results

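The series asked how the transcripts of A549 cells change when the long noncoding RNA LINC00525 is silenced. Its title places the question around p21, the cyclin-dependent kinase inhibitor encoded by CDKN1A. Arrays were deposited for 3 control samples and 3 LINC00525-silenced samples, called knockdown arrays here. The titles mark both groups as "sh", while the treatment text describes small interfering RNA. The genotype fields of knockdown replicates 2 and 3 name LINC00526 and LINC00527 in place of LINC00525, although titles and design text name LINC00525 throughout. The first principal component held 64.8% of the variance of the 18132 genes, and the second held 10.5%. The first separated the groups.

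LINC00525, the silenced transcript, had the lower signal on the knockdown arrays, and CDKN1A had the higher. LINC00525 fell from 3.86 ± 0.12 to 3.55 ± 0.11 log2 units (SD, n = 3 each), a change of -0.30 ± 0.075 (SE; limma adjusted p = 0.0372), so that the signal was 19.0% lower. The exact permutation test gave p = 0.1, the smallest value it can give. Its single probe set lay near background: the 17 Tag control probe sets, which match no human transcript, ranged from 2.27 to 4.60 on the control arrays, with a median of 2.75, and 1 of the 17 lay above LINC00525. CDKN1A rose from 9.54 ± 0.049 to 10.09 ± 0.090 (SD, n = 3 each), or 1.47-fold (log2 0.55 ± 0.055 SE, limma adjusted p = 0.00089), and its second probe set rose 1.51-fold. For each CDKN1A probe set the exact permutation p was 0.1. LINC00526, which 1 genotype field names, was at 4.04 ± 0.085 on control and 4.21 ± 0.10 on knockdown arrays (SD, n = 3 each, limma adjusted p = 0.149). On knockdown replicates 1, 2 and 3 LINC00525 was at 3.67, 3.45 and 3.54, and LINC00526 at 4.28, 4.25 and 4.09. LINC00527 had no probe set of its own and was not measured. The LINC00525 call was lost when control replicate 1, control replicate 3, knockdown replicate 2 or knockdown replicate 3 was left out (adjusted p of 0.096 to 0.111), and without variance moderation (adjusted p = 0.151).

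Of the 22 measured genes of the list built around the study's subject, 3 rose, 6 fell and 13 did not pass the test. Adjusted over the list alone, 4 rose and 8 fell. Besides CDKN1A, the genes that rose were MDM2, an E3 ubiquitin ligase and itself a p53 target (log2 0.37 ± 0.063 SE, limma adjusted p = 0.00928), and CDKN1B, the p27 kinase inhibitor (log2 0.19 ± 0.036). Other MDM2 probe sets were mixed. Those at 0.19, 0.39 and 0.58 passed (limma adjusted p = 0.0347, 0.00959 and 0.00132 over all probe sets), and the rest, at 0 to 0.40, did not. The CDKN1B call rested on a probe set with the suffix _s_at, and 1 without that suffix gave 0.05 ± 0.041 (adjusted p = 0.485). Scaled to the bacterial hybridization controls, the change was -0.09 for CDKN1B and 0.09 for MDM2, whose call was lost (adjusted p = 0.352). EZH2, the histone methyltransferase of Polycomb repressive complex 2, fell by 0.29 ± 0.047 (SE, limma adjusted p = 0.00767), and EED of the same complex fell by 0.19 ± 0.043. For SUZ12, RBBP4 and RBBP7, other subunits of the complex, log2 changes were -0.11, -0.13 and -0.14, none past the threshold. CCNE2, which encodes the S-phase cyclin E2, fell by 0.72 ± 0.11, and by 0.30 at its second probe set. RB1 fell by 0.24 ± 0.053 and E2F1 by 0.22 ± 0.046. The call was lost for EED on leaving out any array but knockdown replicate 3 (adjusted p of 0.0615 to 0.0977), for RB1 any but knockdown replicate 1 (0.0503 to 0.0758), for E2F1 any control array (0.0624 to 0.0806) and for CDKN1B control replicate 2 (0.0628). The other RB1 probe sets gave 0.04 and 0.10, and with the probe sets of a gene averaged RB1 was at -0.03 (adjusted p = 0.728) and EED at -0.10 (adjusted p = 0.0852). Log2 changes did not pass the test for the RNA-binding protein RBMS2 (0.09 ± 0.064, and -0.19 when scaled to the hybridization controls), CDK2 (-0.11), CDK4 (-0.04), CDK6 (0.01, and -0.28 when so scaled), CCND1 (0.13, and -0.16 when so scaled), CCNE1 (-0.10), CDKN1C (-0.04), CDKN2A (-0.05) or CDKN2B (-0.14). The RBMS2 probe sets were mixed. Those at 0.37 and 0.23 passed (limma adjusted p = 0.00545 and 0.037 over all probe sets), and the other ones, at -0.18 to 0.21, did not. Which genes of this list pass depends on the processing. Scaled to the hybridization controls, CDK6, SUZ12, RBBP4, RBBP7, CDK2, CDK4, CCNE1, CDKN1C, CDKN2A and CDKN2B were past the threshold at -0.42 to -0.28, and scaled to the poly-A controls all of these but CDK6 and CDKN2A were, at -0.28 to -0.18. The hybridization scaling lowers every gene by 0.281. Control signals of CDKN1C (4.22), CDKN2A (3.79) and CDKN2B (3.07) lay within the range of the Tag probe sets (2.27 to 4.60). Their calls under scaling can therefore be background shifted down. Of the other alternatives, 4 called RBBP7, 3 RBBP4, 3 CCND1, 1 SUZ12 and 1 CCNE1. As a whole the list was not called by camera (adjusted p = 0.208), and fry called it as lowered (adjusted p = 0.0122).

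**Figure D1:**
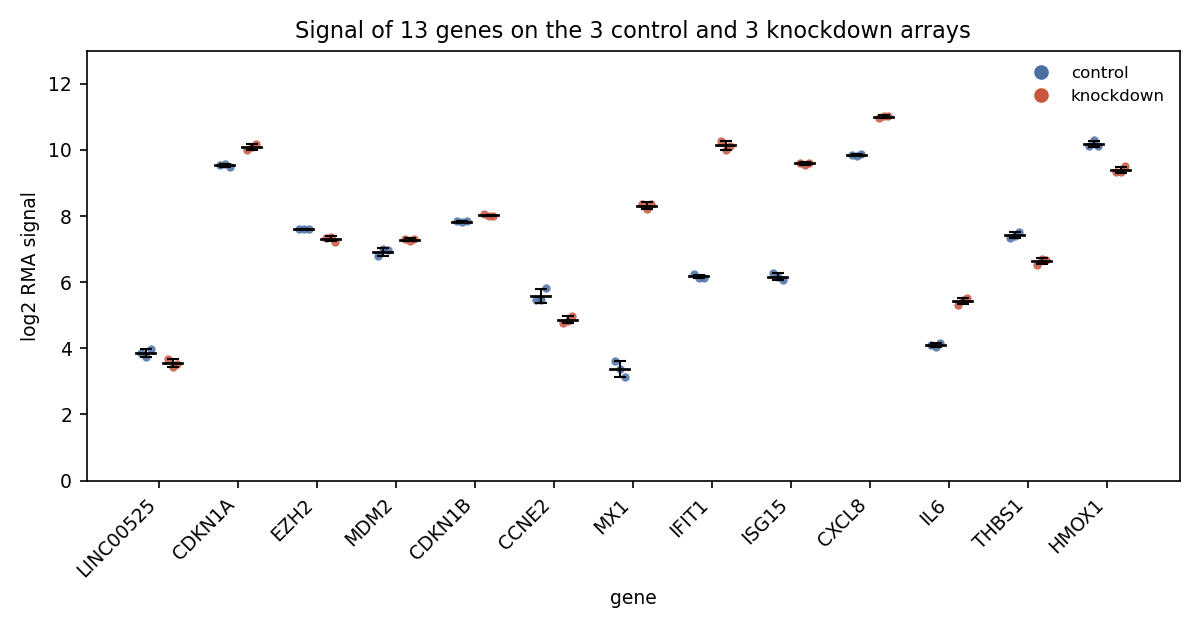
Log2 RMA signal (vertical axis) of 13 genes (horizontal axis) on the 3 control and 3 knockdown arrays; points are arrays, long bars are group means and error bars are SD. MX1 went from 3.37 to 8.32 and CDKN1A from 9.54 to 10.09, while LINC00525 stayed at the low end of the scale in both groups.

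Relative to the typical gene of the array, most of the large changes were rises. Past the threshold were 2285 of 18132 genes (12.6%), of which 1046 rose and 1239 fell. Of the 151 genes that also changed at least 1.5-fold, 143 rose and 8 fell. At least a 2-fold rise was seen in 61 genes and at least a 2-fold fall in 0 (limma adjusted p under 0.05; 4814 genes had an unadjusted p under 0.05). The largest fall was 1.73-fold. The groups did not overlap for 30.8% of genes, against 10% by chance. The split between rises and falls depends on scaling: it was 1290 against 909 after cyclic loess. Bacterial hybridization controls had a higher signal on the knockdown arrays, by 0.28 log2 units (9.22 ± 0.11 against 9.50 ± 0.045, SD, n = 3 each). Scaled to them, the median gene moved by -0.28 and the split was 232 rises against 15085 falls, and 75 against 240 among changes of at least 1.5-fold. Poly-A controls were higher by 0.14, and scaled to them it was 497 against 8397, and 108 against 35 at 1.5-fold or more. All changes here are therefore relative to the typical gene of the array. When control replicate 1, 2 or 3 or knockdown replicate 2 was left out, 1330, 1104, 1258 and 1224 genes passed.

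Interferon-stimulated genes, the antiviral programme that cells switch on after sensing foreign RNA or interferon, made up all 12 largest rises named by the rule. Of 38 measured members 34 rose, 0 fell and 4 did not pass, and 37 rose when adjusted over the list alone. The median change was 2.84-fold. MX1, a GTPase that blocks viral replication, rose 30.8-fold (log2 4.94 ± 0.12 SE, limma adjusted p = 7.33e-07). IFIT1 and IFIT2, which bind foreign RNA, rose 15.6-fold and 10.1-fold, and IFIT3 rose by 3.46 on the log2 scale. IFITM1 rose 12.2-fold, IFI27 11.6-fold, IFI44 11.5-fold, the ubiquitin-like modifier ISG15 10.7-fold and IFI6 8.63-fold. The cytosolic RNA sensors IFIH1 and RIGI rose 7.67-fold and 6.19-fold, and OASL rose 5.19-fold. Control signals of MX1 (3.37), IFI44 (3.56) and IFIH1 (3.80) were low, with 2, 2 and 1 of the 17 Tag control probe sets above them, so their ratios can include background. The size of some rises depends on the probe set: with the probe sets of a gene averaged, the log2 change went from 3.53 to 1.56 for IFI44, from 2.94 to 1.73 for IFIH1 and from 3.54 to 2.88 for IFI27, all still past the threshold. Among the interferons themselves, which are members of this list, IFNB1 rose from 3.01 to 3.27 (log2 0.26 ± 0.043 SE, limma adjusted p = 0.00878; -0.03 when scaled to the hybridization controls), and IFNL1 went from 3.07 to 3.33 without passing the test (adjusted p = 0.159), with 5 of the 17 Tag probe sets above the control signal of each. The list was called by camera (adjusted p = 1.55e-52, and adjusted p = 0.0299 with an estimated correlation). Probe sets for IFI27, IFIT3 and OASL carry the suffix _x_at and can bind related transcripts.

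Antigen presentation genes rose with them. Of 18 measured members 11 rose and 0 fell, and adjusted over the list alone 12 rose and 1 fell. The peptide transporter TAP1 rose 1.67-fold, the immunoproteasome subunit PSMB8 1.46-fold, HLA-F 2.24-fold and HLA-B 1.73-fold (log2 0.79 ± 0.055 SE). HLA genes are close paralogs, and the probe sets used for HLA-B and HLA-F carry the suffix _x_at, so these rises can include related transcripts. Of the HLA-F probe sets without it, 1 gave a log2 change of 1.35 and another 0.32 (limma adjusted p = 2.95e-05 and 0.00724 over all probe sets), and those at 0.14, 0.14 and 0.05 did not pass. With its probe sets averaged, HLA-F was at 0.50 (adjusted p = 0.000113). The 1 HLA-B probe set without it lay near background (mean 3.22) and gave a log2 change of 0.03 ± 0.11 (limma adjusted p = 0.911). The list was called (camera adjusted p = 1.03e-11, and adjusted p = 0.0445 with an estimated correlation). Its mean log2 change was 0.37, and 0.09 when scaled to the hybridization controls, where it was still called. Leukocyte markers did not follow: of 18 measured, 1 rose, the lysosomal protein CD68 (log2 0.61 ± 0.053), and the median log2 change was -0.04 and the mean 0.002 (camera adjusted p = 0.849).

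Inflammatory NF-kB target genes, secreted factors associated with senescence and immediate early genes of the MAPK pathway rose as well. Of the 23 measured NF-kB genes 21 rose and 0 fell (22 rose when adjusted over the list alone; median 1.52-fold). Of the 26 genes of the list of secreted factors 18 rose and 1 fell (20 and 1 over the list alone), and of the 26 MAPK genes 20 rose and 1 fell (21 and 1 over the list alone). The chemokines CXCL8, CXCL2 and CCL20 rose 2.22-fold, 2.14-fold and 2.46-fold. The cytokine IL6 rose 2.53-fold, from a control signal of 4.09 (1 of the 17 Tag probe sets above it) and by a log2 change of 0.70 with its probe sets averaged, and the prostaglandin synthase PTGS2 rose 2.11-fold. Among MAPK genes the EGF receptor ligand EREG rose 2.73-fold (log2 1.45 ± 0.073 SE, limma adjusted p = 3.09e-05), the phosphatases DUSP5 and DUSP1 rose 2.52-fold and 2.16-fold, and IER3 rose 1.88-fold. The MAPK gene that fell was SPRED2, an inhibitor of that pathway (log2 -0.18), whose call was lost on leaving out any of the 6 arrays (adjusted p of 0.0577 to 0.123) and whose other probe sets gave 0.09 and -0.05. The 1 member of the list of secreted factors that fell was LMNB1, the nuclear lamin B1 (log2 -0.42, limma adjusted p = 0.0113). It was put on that list as a gene known to be lost in senescence and is not itself secreted. Camera adjusted p was 4.71e-29 for the NF-kB list, 1.94e-20 for the secreted factors and 3.33e-18 for the MAPK genes. With an estimated correlation these were adjusted p = 0.0299, adjusted p = 0.0349 and adjusted p = 0.0349. The NF-kB list and the secreted factors share 9 measured genes. Scaled to the hybridization controls, the mean log2 change of these 3 lists went from 0.70, 0.56 and 0.48 to 0.42, 0.28 and 0.19.

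Genes of DNA replication and mitosis fell together by small amounts. Of 40 measured genes of the G1/S transition and DNA replication 35 fell, 0 rose and 5 did not pass (39 fell when adjusted over the list alone), with a median log2 change of -0.27. Besides CCNE2, the replication helicase subunit GINS3 fell by 0.53 ± 0.041 (SE, limma adjusted p = 0.000255), the ubiquitin ligase adaptor DTL by 0.47 ± 0.041, the flap endonuclease FEN1 by 0.44 ± 0.040 and the clamp loader subunit RFC5 by 0.41 ± 0.038. Of 41 measured genes of G2/M and mitosis 26 fell and 0 rose (33 fell over the list alone), with a median of -0.18. The kinetochore protein CENPF fell by 0.45 ± 0.057, the mitotic kinesin KIF11 by 0.37 ± 0.043, GTSE1 by 0.36 ± 0.039 and the spindle checkpoint kinase TTK by 0.28 ± 0.038. Both lists were called (camera adjusted p = 1.44e-23 and 5.10e-15), and the calls held with an estimated correlation (adjusted p = 0.0445 and adjusted p = 0.0349). Of 22 measured replication-dependent histone genes 3 fell and 0 rose, also over the list alone, and the list was not called by camera (adjusted p = 0.103) but was called as lowered by fry (adjusted p = 0.000291). They were H1-4, H2BC11 and H2BC12, with log2 changes of -0.39, -0.33 and -0.19. The call was lost for H2BC12 on leaving out any of the 6 arrays (adjusted p of 0.0639 to 0.126), for H1-4 any but control replicate 2 (0.0769 to 0.123), and for H2BC11 without _s_at and _x_at probe sets (0.619).

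The lists of p53 targets, of the ATF4 and amino acid response and of endoplasmic reticulum chaperones held more rises than falls. Of 33 measured p53 target genes 14 rose and 1 fell (17 and 1 over the list alone). GDF15, a stress cytokine, rose 2.08-fold, GADD45A, a DNA-damage response gene, rose 1.86-fold and BBC3, the pro-apoptotic protein PUMA, rose 1.79-fold. KITLG was the member that fell (log2 -0.14), a call lost on leaving out any of the 6 arrays (adjusted p of 0.0736 to 0.121). CDKN1A is a member and is the gene of the study's title, so its rise is not separate evidence of the direction of the list. The list was called at the preset correlation (camera adjusted p = 4.31e-09) and lost with an estimated one (adjusted p = 0.0906). Of 32 measured genes of the ATF4 and amino acid response 11 rose and 1 fell (14 and 1 over the list alone), among them DDIT3, the transcription factor CHOP (2.47-fold), the secreted glycoprotein STC2 (1.64-fold) and DDIT4 (1.26-fold). SLC7A5, an amino acid transporter, was the member that fell (log2 -0.21), a call lost without control replicate 2, control replicate 3 or knockdown replicate 2 (adjusted p of 0.0635 to 0.0694). This list was called both ways (camera adjusted p = 3.55e-05, and adjusted p = 0.0445 with an estimated correlation). Of 25 endoplasmic reticulum chaperone genes 13 rose and 0 fell (15 over the list alone), with DNAJB9 at 1.58-fold, HERPUD1 at 1.32-fold and HYOU1 at 1.29-fold. Another HYOU1 probe set gave a log2 change of 0.41 (limma adjusted p = 0.00439 over all probe sets). Its remaining probe sets, at 0.04 to 0.19, did not pass. For the chaperone list camera adjusted p was 1.79e-10, and with an estimated correlation it was adjusted p = 0.0571. Scaled to the hybridization controls, the mean log2 change of these 3 lists turned from 0.21, 0.16 and 0.17 to -0.07, -0.12 and -0.11, so their rise is relative to other genes.

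The 12 largest falls named by the rule came from several gene groups. THBS1, the matrix protein thrombospondin 1, fell 1.73-fold (log2 -0.79 ± 0.064 SE, limma adjusted p = 0.000358). HMOX1, the haem-degrading enzyme haem oxygenase 1, fell 1.72-fold, and AXIN2, a negative regulator and target of Wnt signalling, fell 1.71-fold. CCNE2 fell 1.65-fold, FAM111B 1.56-fold, the protocadherin PCDH9 1.55-fold, NBPF1 1.54-fold, the heterochromatin protein CBX5 1.49-fold, the transcription factor E2F8 1.47-fold, CHML 1.46-fold and GINS3 1.45-fold. The deiodinase DIO2 fell by 0.59 on the log2 scale. The size of some falls depends on the probe set. With the probe sets of a gene averaged, THBS1 was at -0.435, AXIN2 at -0.553, CCNE2 at -0.51, DIO2 at -0.315 and CBX5 at -0.348. Without its _x_at probe set, E2F8 went from -0.557 to -0.293. All of these were still past the threshold. The other probe sets of HMOX1 and FAM111B fell at least as much as those used. NBPF1 belongs to a family of near-identical copies and was read by an _x_at probe set, so its fall cannot be assigned to 1 member. The FAM111B call was lost without control replicate 2 (adjusted p = 0.053), control replicate 3 (0.0721), knockdown replicate 1 (0.0527) or knockdown replicate 2 (0.0666), and the calls of FAM111B and CCNE2 were lost without variance moderation (adjusted p of 0.122 and 0.0672).

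Among lists of metabolism, growth and chromatin, 4 were called as lowered at the preset correlation and none with an estimated one. Of 27 NRF2 target genes 7 fell and 1 rose (10 and 1 over the list alone). Besides HMOX1 these included GCLC, a glutathione synthesis enzyme (log2 -0.45 ± 0.039 SE), SRXN1 (-0.25) and GPX2 (-0.22). SLC6A6, a taurine transporter, was the member that rose (0.19, but -0.10 when scaled to the hybridization controls). Its camera adjusted p was 0.00133, and with an estimated correlation it was adjusted p = 0.177. Of 29 MYC and ribosome biogenesis genes 7 fell and 1 rose (11 and 1 over the list alone), with the RNA polymerase I subunit POLR1A at -0.39. The member that rose was MYC itself (0.18, but -0.10 when scaled to the hybridization controls). For this list camera adjusted p was 0.000458, and with an estimated correlation it was adjusted p = 0.231. Of 15 fatty acid synthesis genes 3 fell and 1 rose (4 and 1 over the list alone), with GPAM at -0.36, SREBF1 at -0.29 and ME1 at -0.22 against ACSS2 at 0.30 (camera adjusted p = 0.0228, adjusted p = 0.164 with an estimated correlation). Of 32 chromatin regulators 9 fell and 2 rose (9 and 3 over the list alone), with UHRF1 at -0.30, CBX2 at -0.22 and NSD2 at -0.19 against KDM5B at 0.28 and CBX7 at 0.15, which turned to -0.13 when scaled to the hybridization controls (camera adjusted p = 0.034, adjusted p = 0.231 with an estimated correlation). The other CBX2 probe sets, at low signal (means of 2.77 and 3.35), gave 0.08 and 0.07. With its probe sets averaged, CBX2 was at -0.02. The fatty acid call was lost without knockdown replicate 1 (adjusted p = 0.0607) and when scaled to the hybridization or poly-A controls (0.152 and 0.112). The chromatin call was lost without control replicate 2 (0.0763), control replicate 3 (0.095) or knockdown replicate 1 (0.154), under both scalings (0.13 and 0.112) and with probe sets averaged (0.0551). Developmental regulators known to be repressed by Polycomb complex 2 were not called (camera adjusted p = 0.849). Of 36 measured 1 rose, GATA6 at 0.25, which turned to -0.04 when scaled to the hybridization controls, and 1 fell, HOXC6 at -0.22 (1 and 0 over the list alone). Among the genes of these lists, the call was lost on leaving out any array for CBX7, any but knockdown replicate 3 for SLC6A6, any but knockdown replicate 1 for MYC, any but knockdown replicate 2 for ME1, any but control replicate 2 for ACSS2 and any control array for KDM5B (adjusted p of 0.0515 to 0.11). It was also lost for GPX2 without control replicate 2 or any knockdown array, HOXC6 without control replicate 1 or 2 or knockdown replicate 1 or 3, GATA6 and NSD2 without control replicate 1 or 2, CBX2 without control replicate 3 or knockdown replicate 2, and GPAM without control replicate 2 (0.0502 to 0.104).

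Camera at the preset correlation called no housekeeping list and no list of markers of other cell types. Of 34 cytosolic ribosomal protein genes 0 passed the test in limma, nor had any an unadjusted p under 0.05 (camera adjusted p = 0.248). Of 19 heat shock genes 0 passed in limma, and 4 had an unadjusted p under 0.05, among them HSPA8 at -0.09 and DNAJB1 at -0.12 (camera adjusted p = 0.0552). That list was called when the probe sets of a gene were averaged (adjusted p = 0.0165), without knockdown replicate 3 (adjusted p = 0.025) and by fry (adjusted p = 0.0122). Of 31 oxidative phosphorylation genes 1 fell, ATP5PB at -0.17, a call lost on leaving out any of the 6 arrays (adjusted p of 0.066 to 0.13), and 0 fell over the list alone. Camera gave that list an adjusted p of 0.321, and fry called it as lowered (adjusted p = 0.0323). Of 24 markers of alveolar and airway epithelium 2 rose, LAMP3 at 0.79 and ETV5 at 0.27, which turned to -0.01 when scaled to the hybridization controls (camera adjusted p = 0.103). LAMP3 went from 3.15 to 3.93, with 5 and then 1 of the 17 Tag probe sets above it, and its second probe set gave -0.02. The ETV5 call was lost without control replicate 2 (adjusted p = 0.0529) or knockdown replicate 2 (0.0505). No marker of fibroblasts (15 measured), endothelium (12), hepatocytes (14) or neuroendocrine cells (11) passed the test in limma, and 1, 1, 3 and 3 had an unadjusted p under 0.05, with camera adjusted p of 0.849, 0.849, 0.849 and 0.491. The ratio of 3' to 5' signal, a sign of RNA quality, was -0.13 ± 0.015 on control and -0.16 ± 0.006 on knockdown arrays for GAPDH, and 0.42 ± 0.035 and 0.43 ± 0.029 for ACTB (log2, SD, n = 3 each, exact permutation p = 0.1 and 0.9). The signal of 18S ribosomal RNA was 12.38 ± 0.038 on control and 12.15 ± 0.11 on knockdown arrays, a difference of -0.23 (SD, n = 3 each, exact permutation p = 0.1).

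**Figure D2:**
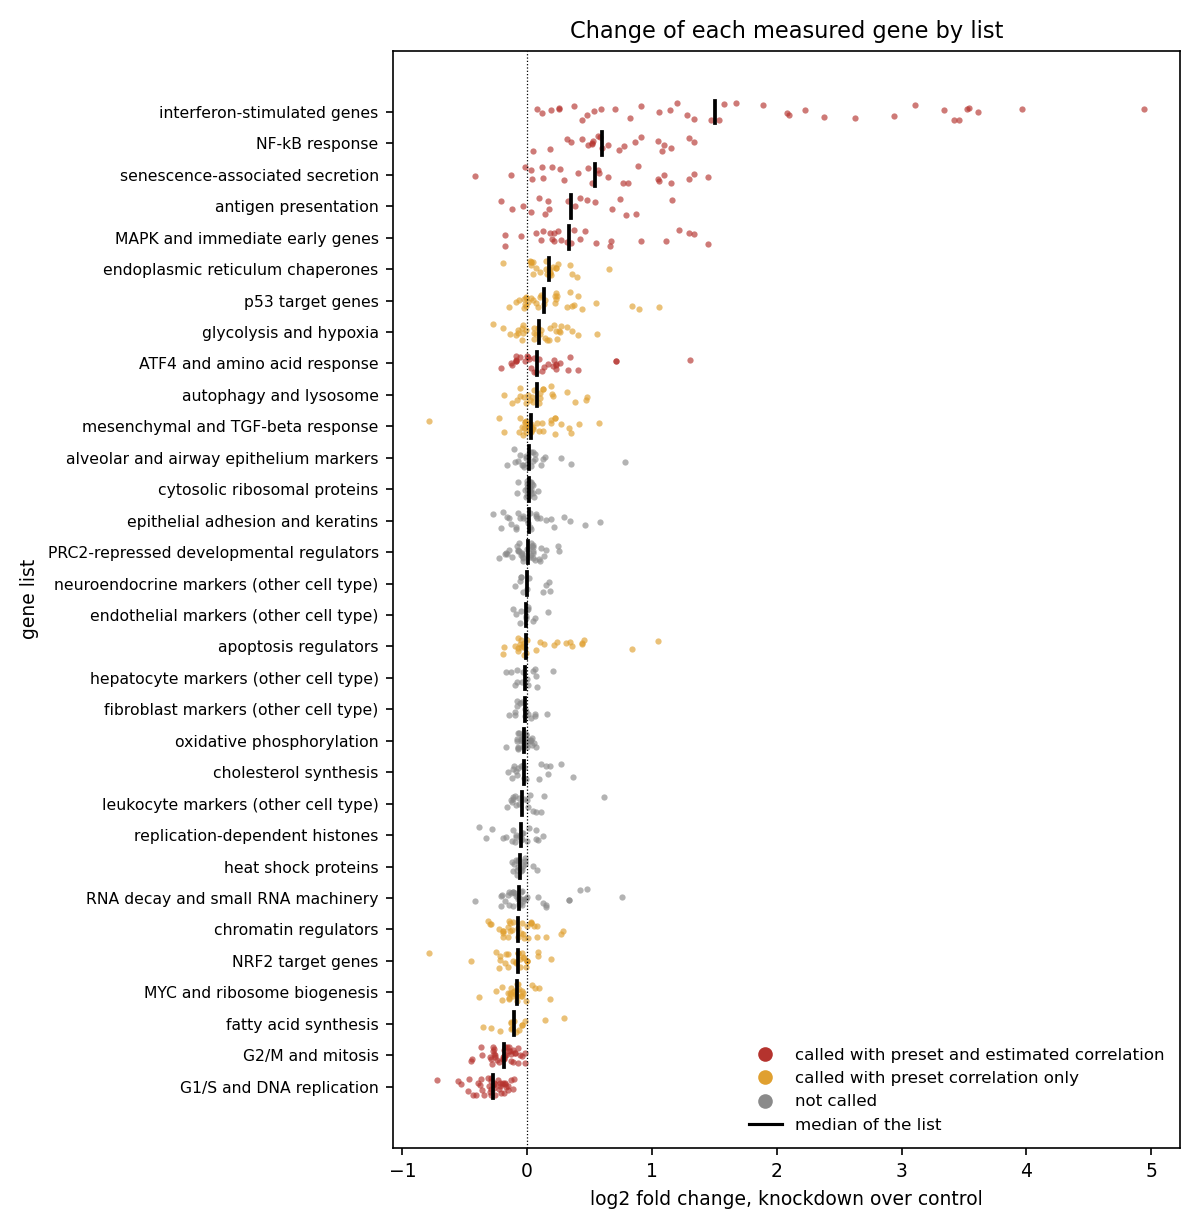
Log2 fold change, knockdown over control (horizontal axis), of each measured gene in 32 fixed lists (vertical axis); points are genes, vertical bars are list medians, and colour gives the camera call. The interferon-stimulated genes have a median of 1.51 and reach 4.94, and the G1/S and G2/M lists have medians of -0.27 and -0.18.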

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

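The predictions for the splits of the arrays were written after the splits had been seen, and the rule for the added controls was made stricter after its value had been seen. The tests of leukocyte markers, of IFNB1, of the added controls at matched signal and of the LINC00525 probe set, and the scalings to added controls, were chosen after their results had been seen.

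Bacterial RNA added as a control, which is not part of the comparison of genes, gave more signal on the knockdown arrays. The 18 probe sets of the hybridization controls were higher by a mean of 0.281 log2 units, and the 24 probe sets of the poly-A controls by 0.141, with all 3 knockdown arrays above all 3 control arrays in both classes (exact permutation p = 0.1, the smallest possible). The 17 Tag probe sets differed by 0.009. At a control signal of 6 to 9 the shifts were 0.347 and 0.139, a difference of 0.208 with a standard error of 0.103 over arrays and a 95% interval of -0.136 to 0.553, so 1 shift common to all added controls cannot be told apart from separate shifts with 3 arrays per group. The 3 probe sets of 18S ribosomal RNA differed by -0.228 (12.4 against 12.2, exact permutation p = 0.1). Unequal addition of the controls and less cellular RNA per array both stay open.

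The rise of the interferon-stimulated genes is the dominant pattern. Leukocyte RNA, unlikely in a cell line, is argued against by the leukocyte markers, whose median log2 change was -0.043 (SD 0.176 over 18 markers). Scaling to the hybridization controls lowers every gene by 0.281, which left a mean rise of 1.487. A uniform shift of that size therefore does not account for the rise. Effects of normalization that depend on signal are not tested by this scaling. A candidate explanation is that cells sensed the introduced small RNA itself, and another is that loss of LINC00525 raised these genes. The treatment text describes a scrambled control, so the first would need a response that differed between the reagents of the groups. IFNB1, near background, rose by 0.26 log2 units, a rise that both explanations allow, so with 1 knockdown group they cannot be told apart. Scaled to the hybridization controls IFNB1 was at -0.025, which follows from the shift of every gene. The Tag probe sets differed by only 0.009 before scaling. For a gene near background, the lost rise therefore does not show that the rise came from scaling. The replication genes, CDKN1A and NF-kB genes moved in the same arrays, so the same question is open for them.

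The measured fall of LINC00525 was small, at 19.0%. Its control signal was only 1.11 log2 units above the median Tag probe set, with 1 of the 17 above it, which is what a probe set near background would show, since background does not fall with the transcript. Incomplete silencing remains possible and cannot be told apart from it, because the 19.0% includes that background.

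The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 of 10 with the most genes past the threshold (2285, highest other 0), the 1 of 10 with the most genes changed at least 1.5-fold (151, highest other 0), and the 1 of 10 with the most lists called (18, highest other 14). The other splits mix the groups 2 to 1 and so carry part of the difference between them, and they called 7 to 14 lists at the preset correlation.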

How the results depend on the processing

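Scaling to the controls and leaving out _s_at and _x_at probe sets were chosen after seeing the data. The 2285 calls became 4539 with each probe set on its own (44994 tested), 3502 with trend and robust eBayes, 1314 without moderation, 822 at an adjusted p under 0.01, 15317 scaled to the hybridization controls and 8894 scaled to the poly-A controls. Of the 2285 genes, 1128 remained called in the same direction without moderation, 1470 with the hybridization scaling and 1730 with the poly-A scaling. Leaving out 1 array gave 1104 to 1575. The 151 calls of at least 1.5-fold became 363 with each probe set on its own and 315 scaled to the hybridization controls (75 rises, 240 falls), and 149 to 168 when 1 array was left out. With the replicate block, 1565 genes and 18 lists were called. The labels do not say whether the numbers pair the samples, and they were not taken to do so. This is therefore not read as a paired result. LINC00525 kept its direction in all 18 alternatives that tested it (both filters on mean signal remove it), with the same value of -0.303 but no call without moderation, and -0.362 to -0.247 when 1 array was left out. Its knockdown values all lay below its control values, so leaving out 1 array could not turn the sign. Settings that alter only the variance could not turn it either. CDKN1A stayed past the threshold in all 20, at 0.272 to 0.598. Of 33 lists, 18 were called, 8 with an estimated correlation, 22 with fry and 16 to 19 when 1 array was left out. Of the 24 genes with the largest changes, 22 kept their call in every alternative that tested them, the exceptions being CCNE2 (1 alternative) and FAM111B (5). Of all 128 named genes past the threshold, 62 kept their call in every alternative that tested them and 66 lost it in at least 1. Scaled to the hybridization controls, 29 of the 178 named genes changed sign, 12 of them past the threshold in neither fit. The other 17 were CDK6 (-0.275), CDKN1B (-0.091), INSIG1 (-0.015), HMGCS1 (-0.101), P4HA2 (-0.021), RPS9 (-0.198), RPLP2 (-0.228), ZEB1 (-0.061), GATA6 (-0.035), ETV5 (-0.008), TIE1 (-0.221), SLC6A6 (-0.095), MYC (-0.098), DSP (-0.128), CBX7 (-0.131), IFNB1 (-0.025) and UPP1 (-0.011), which follows from the shift of -0.281 for every gene. The cause was not tested for the other changes. Low signal limits LINC00525 and other genes near the Tag probe sets.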

Other observations

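The test of neighbouring genes and the scaling to the hybridization controls were chosen after values had been seen. Several lists not described above held genes that moved. Of 28 apoptosis regulators 10 rose and 1 fell, BIRC5 at -0.19 (10 and 2 adjusted over the list alone). The rises included the anti-apoptotic genes BCL2A1 (2.07-fold), MCL1 (1.37-fold) and CFLAR (1.36-fold), beside the pro-apoptotic BBC3. The size of these anti-apoptotic rises depends on the probe set. Other probe sets gave log2 changes of -0.003 to 0.33 for MCL1 and -0.003 to 0.46 for CFLAR. The second BCL2A1 probe set, near background (mean 2.28), gave 0.05. The list was called as raised (camera adjusted p = 0.00212, adjusted p = 0.177 with an estimated correlation), with a mean of 0.14 but a median of -0.01. Of 24 autophagy and lysosome genes 6 rose and 0 fell in limma (9 and 1 over the list alone; 11 had an unadjusted p under 0.05), with the cholesterol transporter NPC1 at 1.40-fold and WIPI1 at 1.39-fold (camera adjusted p = 0.000468, adjusted p = 0.239 with an estimated correlation). Of 32 glycolysis and hypoxia genes 10 rose and 2 fell, PFKFB3 at -0.19 and PGAM1 at -0.14 (14 and 3 over the list alone), with ANGPTL4 at 1.48-fold and NDRG1 at 1.28-fold (camera adjusted p = 0.000278, adjusted p = 0.177 with an estimated correlation). Of 36 mesenchymal and TGF-beta genes 8 rose and 2 fell, THBS1 and SMAD7 at -0.22 (8 and 2 over the list alone), with CCN2 at 1.49-fold and BHLHE40 at 1.33-fold (camera adjusted p = 0.0101, adjusted p = 0.271 with an estimated correlation). Scaled to the hybridization controls, the means of these 4 lists were -0.138, -0.18, -0.179 and -0.221. The mesenchymal call was lost there (adjusted p = 0.13), without knockdown replicate 2 (adjusted p = 0.0602) and with fry (adjusted p = 0.0513). Among the members that fell, the call was lost on leaving out any array for PGAM1, any but knockdown replicate 2 for PFKFB3, any control array for SMAD7, and control replicate 2, control replicate 3 or knockdown replicate 2 for BIRC5 (adjusted p of 0.0508 to 0.127). The other SMAD7 probe sets gave -0.12 and 0.007, and with its probe sets averaged SMAD7 was at -0.11.

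Other lists held changes in both directions or few changes. Of 36 RNA decay and small RNA genes 6 rose and 7 fell, also over the list alone (camera adjusted p = 0.364). Members of the family of zinc-finger proteins that destabilize AU-rich mRNAs moved apart, with ZFP36 at 1.69-fold and ZFP36L1 at 1.26-fold, while ZFP36L2 fell by 0.42 on the log2 scale. Of 28 genes of epithelial adhesion and keratins 4 rose and 3 fell (7 and 4 over the list alone). The tight-junction genes CLDN1 and OCLN rose by 0.58 and 0.46 on the log2 scale, KRT19 by 0.29 and the desmosomal DSP by 0.15 (-0.128 when scaled to the hybridization controls), and ELF3, GRHL2 and KRT8 fell by 0.21, 0.20 and 0.15. Camera gave the list an adjusted p of 0.273, and fry called it as raised (adjusted p = 0.0323). The call was lost for DSP and KRT8 on leaving out any array, for GRHL2 any but knockdown replicate 2 and for ELF3 control replicate 2 (adjusted p of 0.0562 to 0.146). GRHL2 has a mean signal of 3.48 (2 of the 17 Tag probe sets above its control signal), and its other probe sets gave -0.08 to 0.02. Of 19 cholesterol synthesis genes 3 rose, STARD4, INSIG1 and HMGCS1, and 0 fell, also over the list alone (camera adjusted p = 0.66; median -0.03, mean 0.02). INSIG1 and HMGCS1 turned to -0.015 and -0.101 when scaled to the hybridization controls, and the HMGCS1 call was lost on leaving out any array but knockdown replicate 1 (adjusted p of 0.0637 to 0.101).

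A hypothesis was that the p53 target list was raised only through members it shares with other lists. The 23 measured targets found in no other list leave out CDKN1A, MDM2, GDF15 and BBC3. Their mean log2 change was 0.115 and their median 0.067, with 6 rises and 1 fall. Camera gave p = 0.00044, and p = 0.0452 with an estimated correlation, both unadjusted. This argues against the hypothesis, but the second p lies close to 0.05, and GADD45A, at 0.893, is among the 23. The mean is also smaller than the 0.281 by which hybridization controls differed. Likewise the 17 members of the list of secreted factors outside the NF-kB list, LMNB1 among them, had a mean of 0.38, with 9 rises and 1 fall (camera p = 9.05e-10, p = 0.0187 with an estimated correlation), so shared members do not account for the whole of that rise.

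Another hypothesis was that loss of LINC00525 changes its chromosomal neighbours. Of the 20 nearest measured genes, 10 on each side, 2 passed the threshold, IGFBP1 (log2 1.61 ± 0.095 SE, limma adjusted p = 7.4e-05) and UPP1 (0.27 ± 0.044, but -0.011 when scaled to the hybridization controls). This is 10% against 12.6% of all genes (Fisher's exact test, 2-sided, p = 1), so the test shows no excess and, with 20 genes, excludes little. Low signal limits it further. Control signals of C7orf57 (1.91), ABCA13 (1.98), ZPBP (2.16) and SUN3 (2.19) lay below the lowest Tag probe set (2.27), where a change could hardly be seen. Those of PKD1L1-AS1 (2.53), VWC2 (3.06), LOC105375268 (3.06), LINC02902 (3.07), NACAD (3.19), SPMIP7 (3.63), RAMP3 (4.40) and SNORA5A (4.56) lay within the Tag range, which reached 4.60. The share of all genes was not matched to the neighbours for signal. IGFBP1, a secreted binding protein of insulin-like growth factors, was the neighbour with the largest change.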
